A study of Ovis aries with 12 samples.

How the data were processed

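Gene expression was measured in 12 corpora lutea of sheep, 1 per ewe, on Affymetrix bovine expression arrays. The corpus luteum is the ovarian gland that makes progesterone after ovulation. Per the labels' protocols, the glands were snap frozen, total RNA was extracted with Trizol, and the RNA was labelled with biotin through a whole-transcript terminal labelling kit. Per the same protocols, pregnant ewes had been mated with a fertile ram, and non-pregnant ewes were left unmated and checked for heat with a vasectomized ram.

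The deposited table held log2 values for 24128 probe sets, which were made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, normalizes the arrays to one distribution by quantiles and sums the probes of a probe set on the log2 scale. The software version and settings were not given in the sources used here. RMA gives no detection calls, and scanner files were not used here, so a dim probe set cannot be told from one without signal. Sheep RNA was hybridised to probes designed on bovine sequence, so a mismatch between the species lowers a probe set's signal. Levels of different probe sets were therefore not read as relative amounts of their transcripts. They served only to pick the brightest probe set of a gene, to mark dim ones and to match random lists on level.

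Groups were taken from the source label of each sample. The titles name day 12 pregnant for every array, which conflicts with the source label of 9 of the 12, and the titles were not used. Each group had 3 ewes with 1 array each, so p-values of single probe sets measure the spread between separate ewes, pooled over the 4 groups. The number of arrays limits the precision. The description labels are of a pair of kinds, which differ in date and in the name of the array. They call it a gene array for 4 arrays, here batch A, and a genome array for 8, here batch B. Whether these names stand for different array designs or only for separate runs was not settled, although all 12 arrays have values for the same probe sets, so the batch term and values within batches cover either. Batch A held 1 day 12 pregnant, 1 day 14 pregnant and 2 day 14 non-pregnant arrays. Replicate numbers were given in accession order and pair no samples. No array had the same values as another. Quantitative PCR of further samples, which the series' design text mentions, was not analysed here.

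The values were used as deposited, after leaving out 112 control probe sets, which left 24016 tested. Gene symbols came from GEO's annotation of the bovine array. They named 1 gene for 13292 probe sets, several for 86 and none for 10638, which gave 9155 different symbols. None was named from a probe set with several symbols, and 0 of the annotation's gene identifiers occurred in the sheep gene table used here, so bovine symbols were kept as given and can be old.

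A linear model with a mean per group and an additive term for array batch was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 7 residual degrees of freedom and 4.391 prior ones. The moderated test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. There were 4 comparisons between a pair of groups, 1 interaction term for the difference of the pregnancy effect between the days, and 1 average of the pregnancy effect over the days. Values given with ± are log2 differences with their standard error from the fit, unless SD is named. The batch term itself passed for 0 probe sets in limma, against 1658 at an unadjusted p under 0.05.

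There were 30 gene lists with 972 members, for steroid synthesis, luteal signalling, interferon response, the cell types of the gland and general cell functions. Each gene entered once, by its brightest probe set with 1 symbol. The shift of a list against all other genes was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The same test with an estimated correlation and the rotation test fry, which asks only whether a list's genes move one way on balance, were run beside it. Lists under 5 measured members would have been left out, and all 30 had enough. Standard errors of list means are over list members, which are not independent replicates.

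Named genes are the 12 with the largest rise and the 12 with the largest fall among those past the threshold, leaving out unnamed loci. Where none passed, the 5 with the smallest p in each direction are given as values. Up to 4 members with the smallest p were added from each list that shifted or had several members past the threshold. STAR, CYP11A1, HSD3B1, LHCGR, PTGFR, OXT, ISG15, MX1 and VEGFA were fixed reference genes. The groups, comparisons, tests, lists, this naming rule and all alternatives except those named as later were chosen before the data were examined.

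The alternatives were no batch term, batch as a random block, a fit of only the groups compared, a further quantile normalization, arrays shifted to one median, and leaving out the dimmest probe sets (mean log2 level under 4.1478, 16010 left). Others were an intensity trend with robust variance, array weights, thresholds with a 1.5-fold change, fits within each batch, and leaving out each array in turn. Only 6 of the 12 arrays lie in the groups of a pairwise comparison. Leaving out any other array acts only through the batch term and the shared spread, so it cannot show whether a single ewe carries a difference. For lists, the mean over all probe sets of a gene was tried too. A fit without both batch A arrays of the day 14 non-pregnant group and a comparison of results that share arrays were added after seeing the data.

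Simulated data of 24016 probe sets had independent normal noise, with 1 spread per probe set for all groups and no batch effect or correlation between genes. The real day 14 non-pregnant arrays spread more widely than the other groups, so the rates need not hold for comparisons with them. The model was tested on these simulated data with 50 changed probe sets per size. For the day 14 comparison it recovered 26% of 1.41-fold, 90% of 2-fold and 100% of 4-fold changes, with 10 false calls among 168. For day 12 it recovered 18%, 94% and 100%, with 7 false calls among 163. For the change between days it recovered 10%, 90% and 100% in non-pregnant ewes and 30%, 90% and 100% in pregnant ewes, with 15 false calls among 164 and 11 among 171. For the interaction it recovered 0%, 64% and 100%, with 8 false calls among 140. The list test was tested with the interferon-stimulated list of 45 genes shifted by 0.3, which passed, while 0 of 29 other lists did. That simulation, with independent genes, cannot show how camera behaves when genes are correlated.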

Results

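The data comprised log2 expression values of 24016 bovine probe sets in 12 ovine corpora lutea. Pregnant and non-pregnant ewes were sampled on day 12 and on day 14, with 3 ewes and 1 array each per group. Array medians lay between 5.16 and 5.24 on the log2 scale, and differences are log2 differences ± standard error from limma unless another error is named. Per its title, the study asked which genes associated with pregnancy take part in the gland's resistance to luteolysis, the regression of the corpus luteum that ends the cycle of a ewe without a conceptus.

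The 3 day 14 non-pregnant arrays stood apart from the other 9. On the first principal component, which held 29.6% of the variance, they lay at 30.7 ± 11.4 (SD, n = 3), with replicate 1 of batch B at 18.1 and replicates 2 and 3 of batch A at 33.7 and 40.4. All other arrays lay between -13.0 and -7.00, with SDs of 0.884 to 1.96 within their groups. The spread that the model pools over groups can thus be too small for the day 14 non-pregnant group, and p-values that involve it can be too low. Correlations between arrays of one group were 0.987 to 0.988 in the day 14 non-pregnant group and 0.992 to 0.995 in the others. The difference between 3′ and 5′ control probe sets was averaged over actin and GAPDH. It was taken as a sign of RNA integrity, assumed to be higher with more degradation. Whether this holds with the whole-transcript labelling named in the protocols was not tested. The difference was 1.37 ± 0.0731 in the day 14 non-pregnant group and 1.52 ± 0.0823 in the day 14 pregnant group (log2, SD, n = 3). On day 12 it was 1.45 ± 0.031 in non-pregnant and 1.58 ± 0.016 in pregnant ewes. Against the other 9 arrays, a two-sided exact permutation test over 220 splits gave p = 0.0182 for the day 14 non-pregnant group and p = 0.0318 for the day 12 pregnant group, both 0.0636 after Benjamini-Hochberg adjustment over the 4 groups.

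**Figure D1:**
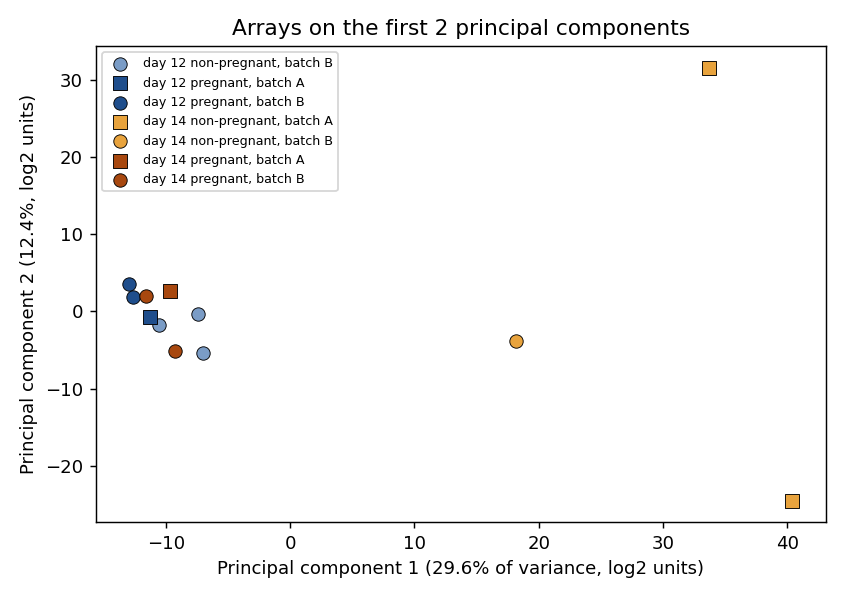
Positions of the 12 arrays on the first principal component (29.6% of the variance, horizontal) and the second (12.4%, vertical), in component units, with one colour per group, circles for batch B and squares for batch A. The 3 day 14 non-pregnant arrays lie between 18.1 and 40.4 on the first component, and the other 9 lie between -13.0 and -7.00.

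The day 14 comparison asked what differs with pregnancy when luteolysis begins in the ewe that is not pregnant. VEGFA, the main angiogenic factor of the gland, was 3.45-fold higher, at 10.5 ± 0.158 against 8.74 ± 0.511 (log2, SD, n = 3; difference 1.79 ± 0.24, adjusted p = 0.00536). NR5A2, a nuclear receptor that drives steroidogenic genes, was higher by 1.16 ± 0.12 (adjusted p = 0.00148). STAR, which carries cholesterol into mitochondria, was higher by 0.74 ± 0.13 (adjusted p = 0.0246). PTHLH, which encodes parathyroid hormone-related protein, was 8.35-fold higher (3.06 ± 0.46, adjusted p = 0.0084). CD34, a surface protein of endothelial cells, was higher by 1.09 ± 0.16 (adjusted p = 0.00828). Of the other steroidogenic and luteal reference genes, CYP11A1 (0.43 ± 0.11, adjusted p = 0.0769), HSD3B1 (0.62 ± 0.14, adjusted p = 0.0556) and PTGFR (0.77 ± 0.22, adjusted p = 0.115) did not pass. Nor did LHCGR (0.37 ± 0.21, adjusted p = 0.446) or OXT (0.063 ± 0.11, adjusted p = 0.831).

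F2RL1, a protease-activated receptor, was lower in pregnant ewes, at 3.82 ± 0.202 against 6.58 ± 0.426 (log2, SD, n = 3; -2.69 ± 0.25, adjusted p = 0.000859). Its level in pregnant ewes lay among those of the dimmest probe sets (under 4.1478), so the size of its difference is uncertain. Its relative F2RL2 was lower (-2.40 ± 0.18, adjusted p = 0.000173, 2 of 3 probe sets past the threshold). TNFRSF12A, the receptor for the cytokine TWEAK, was lower by both of its probe sets, with -2.57 ± 0.32 for the dimmer (adjusted p = 0.00398) and -1.25 ± 0.21 for the brightest (adjusted p = 0.0172). THBS1, a matrix protein that inhibits angiogenesis, was lower by its brightest probe set (-1.93 ± 0.25, adjusted p = 0.00411), with 3 of its 6 probe sets past the threshold. OLR1, a receptor for oxidized LDL (-3.17 ± 0.50, adjusted p = 0.012), PLIN2, a coat protein of lipid droplets (-2.61 ± 0.39, adjusted p = 0.0084), and ABCC3, an efflux transporter (-2.14 ± 0.21, adjusted p = 0.0011), were lower too. So were NDRG1, a stress-induced gene (-2.38 ± 0.27, adjusted p = 0.00248), and MAP1LC3C, an autophagy gene (-2.93 ± 0.36, adjusted p = 0.00352).

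In limma with Benjamini-Hochberg adjustment, 348 probe sets passed on day 14, 129 higher and 219 lower in pregnant ewes, and 227 of them named 205 genes. Within batch A (1 pregnant and 2 non-pregnant arrays) and batch B (2 and 1) the differences were 1.94 and 1.63 for VEGFA, 1.11 and 1.21 for NR5A2, 0.94 and 0.44 for STAR, 2.14 and 4.03 for PTHLH and 1.31 and 0.74 for CD34. They were -2.81 and -2.38 for F2RL1, -2.44 and -2.28 for F2RL2, -2.30 and -2.85 for the dimmer and -1.31 and -1.21 for the brightest TNFRSF12A probe set, and -2.01 and -1.76 for THBS1. For OLR1 they were -4.65 and -1.53, with -2.60 and -2.72 for PLIN2, -2.55 and -1.68 for ABCC3, -2.16 and -2.40 for NDRG1 and -2.72 and -3.01 for MAP1LC3C. NR5A2, PTHLH, F2RL1, F2RL2, THBS1, ABCC3, NDRG1, MAP1LC3C and the dimmer TNFRSF12A probe set passed in each of the 12 leave-outs of 1 array. The brightest TNFRSF12A probe set did not pass without day 14 pregnant replicate 2 or 3 or day 14 non-pregnant replicate 1 (adjusted p = 0.0542, 0.116 and 0.0566). VEGFA, CD34, OLR1 and PLIN2 did not pass without day 14 pregnant replicate 3 (adjusted p = 0.0584, 0.0799, 0.0909 and 0.0788). STAR did not pass without day 14 pregnant replicate 1, 2 or 3 or without day 14 non-pregnant replicate 3 (adjusted p = 0.0597, 0.0612, 0.146 and 0.0506). The count of 348 became 88, 146 and 177 without day 14 pregnant replicates 3, 2 and 1. It was 223 without day 12 pregnant replicate 2, 227 without day 12 non-pregnant replicate 3 and 174 without both batch A arrays of the day 14 non-pregnant group. With only the 6 arrays compared, 24 passed, among them NR5A2, F2RL1, F2RL2, PLIN2, NDRG1, ABCC3 and MAP1LC3C but not VEGFA (adjusted p = 0.0776).

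**Figure D2:**
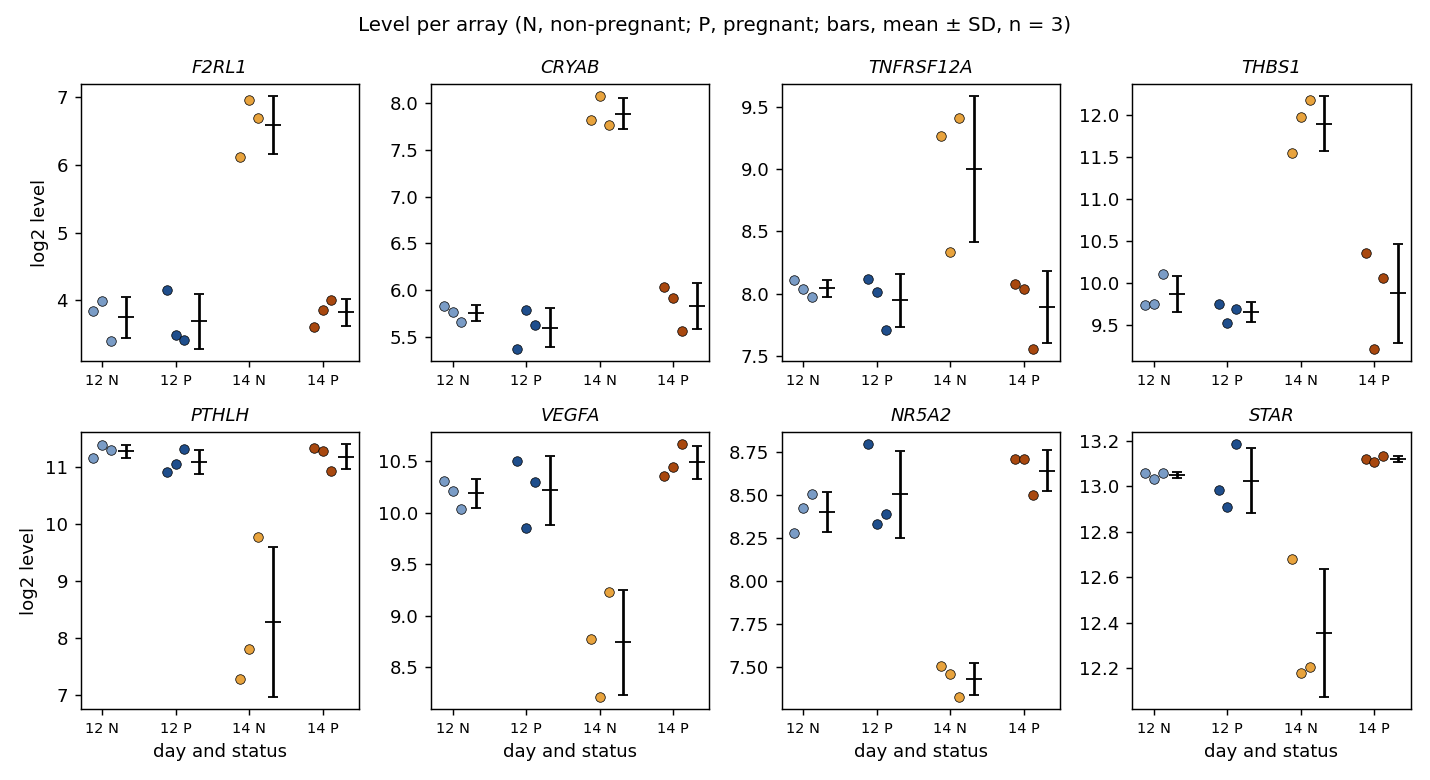
Log2 level (vertical) of the brightest probe set of 8 genes on each of the 12 arrays, as points by group, with the group mean and bars of 1 SD (n = 3). F2RL1 lies at 3.82 in day 14 pregnant and 6.58 in day 14 non-pregnant ewes, and NR5A2 at 8.64 and 7.43.

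Interferon-stimulated genes, which respond to interferons such as the conceptus interferon tau of ruminants, were higher in pregnant ewes on day 14. Of 45 measured members 13 passed over all genes, 27 passed adjusted over the list alone, and 41 lay above 0, with a mean of 0.54 ± 0.055 over members. XAF1 (1.40 ± 0.24, adjusted p = 0.0193), PARP9 (0.88 ± 0.13, adjusted p = 0.00744) and DHX58, an RNA sensor (0.80 ± 0.10, adjusted p = 0.00424), passed. MX1 (1.04 ± 0.24, adjusted p = 0.065) and ISG15 (1.46 ± 0.46, adjusted p = 0.152) did not. The list shifted with camera adjusted p = 1.41e-15, and adjusted p = 0.191 with an estimated correlation. Its mean was 0.54 within batch A and 0.50 within batch B, and it passed in all 12 leave-outs. DHX58 passed in each leave-out, PARP9 did not pass without day 14 pregnant replicate 3 (adjusted p = 0.081), and XAF1 did not pass without replicate 3 (0.078) or 2 (0.0567) of that group. Beside this and the other day 14 lists, the 3′ minus 5′ difference was 1.44 to 1.60 in the pregnant and 1.29 to 1.43 in the non-pregnant arrays. These means came as close as 1.439 and 1.433 without overlap, while the values of actin and of GAPDH taken singly overlapped.

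The progesterone synthesis and cholesterol supply list was higher too. Of its 24 members STAR and NR5A2 were higher and SOAT1, which esterifies cholesterol, was lower (-0.95 ± 0.21, adjusted p = 0.049) over all genes. Adjusted over the list alone, 8 were higher and 1 lower. Its mean was 0.17 ± 0.080, 0.22 ± 0.0901 within batch A and 0.14 ± 0.0784 within batch B (camera adjusted p = 0.0192, adjusted p = 0.191 with an estimated correlation). Cell division genes had 33 of 34 members above 0, with 0 past the threshold in limma over all genes and 7 adjusted over the list alone. Among them MCM3, of the replication helicase, was at 0.49 and TPX2, a spindle factor, at 0.74. Their mean was 0.36 ± 0.042, 0.60 and 0.23 within batches A and B (camera adjusted p = 4.81e-06, adjusted p = 0.574 with an estimated correlation). Class I antigen presentation, which shows peptides to cytotoxic T cells, had 0 of 16 past the threshold over all genes and 5 adjusted over the list alone, with TAP2 at 0.42 and PSMB9 at 0.54. Its mean was 0.21 ± 0.050, with 0.36 ± 0.0658 within batch A and 0.064 ± 0.0913 within batch B, so batch B alone showed no clear shift (camera adjusted p = 0.00226, adjusted p = 0.574 with an estimated correlation).

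There were 5 lists lower in pregnant ewes, beside the same 3′ minus 5′ difference. Some of their means within a batch lay under 2 standard errors over members from 0, so an equal sign in both batches is weak evidence. These errors were 0.152 for the immediate early list and 0.172 for hypoxia in batch B. They were 0.0903 for antioxidant defence and 0.0781 for the unfolded protein response in batch A, and 0.116 and 0.0784 for matrix remodelling in batches A and B. The immediate early and luteolysis response list had 3 of 35 lower over all genes, which were THBS1, TGFB1 (-0.76 ± 0.13, adjusted p = 0.0209) and the dim CXCL8 (-0.59 ± 0.12, adjusted p = 0.0428). Adjusted over the list alone, 2 were higher and 5 lower. Its mean was -0.38 ± 0.129, -0.55 and -0.13 within batches A and B (camera adjusted p = 0.00224, adjusted p = 0.624 with an estimated correlation). In the hypoxia response list NDRG1 and the glucose transporter SLC2A1 (-0.85 ± 0.15, adjusted p = 0.0251) were lower and VEGFA, itself induced by hypoxia, was higher. Adjusted over the list alone, 2 of 23 were higher and 5 lower, and the mean was -0.31 ± 0.169, -0.40 and -0.18 within batches A and B (camera adjusted p = 0.004, adjusted p = 0.191 with an estimated correlation). Antioxidant defence had 3 of 35 lower over all genes, which were the peroxidase PRDX6 (-1.12 ± 0.16, adjusted p = 0.00724), HMOX2 (-1.15 ± 0.19, adjusted p = 0.0161) and MT2A (-1.27 ± 0.27, adjusted p = 0.0451), and 9 lower adjusted over the list alone. Its mean was -0.17 ± 0.085, -0.063 and -0.24 within batches A and B (camera adjusted p = 0.0333, adjusted p = 0.574 with an estimated correlation).

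The unfolded protein response had 1 of 25 lower over all genes (HSPA5, the main chaperone of the endoplasmic reticulum, -0.59 ± 0.12, adjusted p = 0.0389) and 4 lower adjusted over the list alone, with a mean of -0.12 ± 0.065, -0.084 and -0.13 within batches A and B. Extracellular matrix remodelling had 2 of 32 lower over all genes, the protease inhibitor TIMP3 (-1.40 ± 0.23, adjusted p = 0.0153) and the dim collagenase MMP1 (-0.75 ± 0.15, adjusted p = 0.0318). Adjusted over the list alone 1 was higher and 6 lower, and the mean was -0.18 ± 0.092, -0.17 and -0.14 within batches A and B. For both lists camera's adjusted p was 0.0489, and adjusted p = 0.574 with an estimated correlation. Without day 14 pregnant replicate 3, 2 of the 9 lists passed, the interferon-stimulated and antioxidant lists, and the mean was 0.14 for cell division, 0.098 for class I and -0.25 for antioxidant defence. The immediate early mean was -0.59 and -0.705 without day 14 non-pregnant replicates 1 and 2. Without replicate 3 of that group the matrix mean was -0.11 and the mean of the immediate early list was 0.049 (adjusted p = 0.439). The antioxidant, unfolded protein and matrix lists passed in 9, 6 and 5 of the 12 leave-outs, with the highest adjusted p of 0.0803 without day 14 non-pregnant replicate 1, 0.15 without replicate 2 and 0.265 without replicate 3. Of their single genes and those of the luteolysis, hypoxia and progesterone lists, HMOX2, TGFB1, SLC2A1, MMP1, MT2A, HSPA5, SOAT1 and CXCL8 passed in 10, 9, 9, 5, 2, 2, 2 and 1 of the leave-outs. TIMP3 (adjusted p = 0.127) and PRDX6 (0.0747) did not pass without day 14 pregnant replicate 3.

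The other 21 lists did not pass on day 14. For the cell types camera's adjusted p was 0.0508 for T and NK cells, 0.214 for endothelial cells and for neutrophils and eosinophils, 0.215 for fibroblasts and 0.526 for B cells. It was 0.629 for granulosa and follicle, 0.769 for macrophages and for red blood cells and 0.841 for smooth muscle and pericytes. WNT signalling gave 0.123, cholesterol biosynthesis 0.169, ribosomal proteins 0.307, activin, BMP and TGF-beta signalling 0.334, oxidative phosphorylation 0.615 and cell death and survival 0.629. Luteotropic and luteolytic receptors and the insulin-like growth factor system gave 0.685, angiogenic factors and receptors 0.698, class II antigen presentation 0.819, prostaglandin synthesis, transport and breakdown 0.922 and cytokines and chemokines 0.994. Mean and median had opposite signs in 6 of these lists. They were 0.048 and -0.13 for macrophages, -0.17 and 0.013 for granulosa and follicle, and -0.091 and 0.035 for the insulin-like growth factor system. They were -0.056 and 0.068 for class II antigen presentation, 0.036 and -0.0070 for prostaglandins and 0.078 and -0.0073 for cytokines. Camera's direction was down for macrophages and prostaglandins. Among the angiogenic factors VEGFA and the receptors FGFR2 and TIE1 were higher and THBS1 lower over all genes, and FGFR2 and TIE1 passed in 8 and 7 of the 12 leave-outs.

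**Figure D3:**
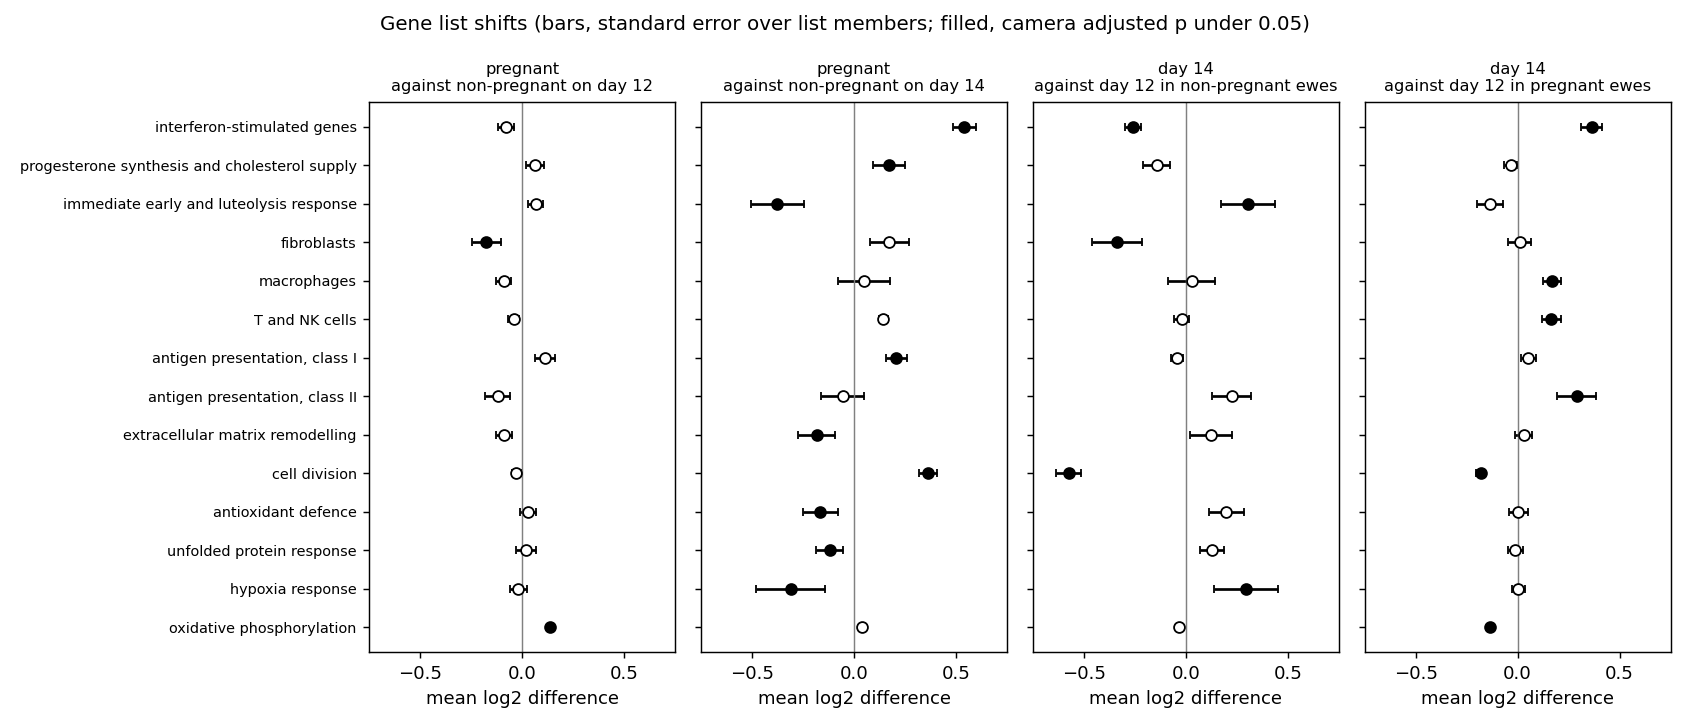
Mean log2 difference (horizontal) of 14 gene lists (vertical) in the 4 comparisons between a pair of groups, with bars of 1 standard error over list members, filled points where camera's adjusted p at the preset correlation was under 0.05. The interferon-stimulated list lies at 0.54 for pregnancy on day 14, -0.26 for the change over days in non-pregnant ewes and 0.36 for that in pregnant ewes.

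From day 12 to day 14 in non-pregnant ewes, the comparison asked how the gland of the cycle changes as luteolysis begins. CRYAB, a small heat shock protein, rose 4.58-fold, from 5.75 to 7.89 (difference 2.20 ± 0.17, n = 3 per group, adjusted p = 0.000362). F2RL1 rose by 2.70 ± 0.28 (adjusted p = 0.0019), from a level of 3.75 among the dimmest probe sets (under 4.1478), so the size of the rise is uncertain. F2RL2 rose by 2.17 ± 0.20 (adjusted p = 0.00127) and ABCC3 by 2.27 ± 0.24 (adjusted p = 0.00216). TNFRSF12A rose by 2.83 ± 0.36 (adjusted p = 0.00855) through its dimmer probe set, while its brightest was at 1.24 ± 0.23 and did not pass (adjusted p = 0.0525). NDRG1 rose by 2.19 ± 0.30 (adjusted p = 0.012) and THBS1 by 1.84 ± 0.27 (adjusted p = 0.018). GCSH, of the mitochondrial glycine cleavage system, fell by 1.05 ± 0.14 (adjusted p = 0.00939). PTHLH fell by 3.33 ± 0.51 (adjusted p = 0.0194) and TGFB2 fell by 1.33 ± 0.19 (adjusted p = 0.0151). VEGFA fell by 1.52 ± 0.26 (adjusted p = 0.0386) and NR5A2 fell by 0.86 ± 0.14 (adjusted p = 0.0239). STAR was at -0.64 ± 0.15 (adjusted p = 0.0992), HSD3B1 at -0.52 (adjusted p = 0.2) and CYP11A1 at -0.34 (adjusted p = 0.273), which did not pass.

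In limma 94 probe sets passed, 70 higher and 24 lower on day 14, and 60 of them named 55 genes. The split was 231 higher and 184 lower without a batch term and 250 and 212 with batch as a random block. Batch A held no day 12 non-pregnant array. Within batch B (1 day 14 and 3 day 12 arrays) the differences were 2.07 for CRYAB, 2.36 for F2RL1, 2.03 for F2RL2, 1.92 for ABCC3, 3.04 for the dimmer and 1.22 for the brightest TNFRSF12A probe set, 2.07 for NDRG1 and 1.68 for THBS1. They were -0.90 for GCSH, -4.01 for PTHLH, -1.41 for TGFB2, -1.41 for VEGFA and -0.90 for NR5A2. CRYAB, F2RL1, F2RL2, ABCC3 and GCSH passed in each of the 12 leave-outs. The dimmer TNFRSF12A probe set did not pass without day 14 non-pregnant replicate 1 (adjusted p = 0.0559), nor NDRG1 without day 12 non-pregnant replicate 2 (0.0664). THBS1 did not pass without day 12 non-pregnant replicate 1 or 2 or day 12 pregnant replicate 3 (0.0663, 0.0893 and 0.0555), nor TGFB2 without day 12 non-pregnant replicate 2 or 3 or day 14 non-pregnant replicate 1 (0.0751, 0.0645 and 0.0845). PTHLH, NR5A2 and VEGFA passed in 7, 7 and 3 of the leave-outs, with the highest adjusted p of 0.115 and 0.103 without day 14 non-pregnant replicate 1 and 0.139 without day 12 non-pregnant replicate 2. None of these genes passed when only the 6 arrays compared were fitted, where 1 probe set did. The count of 94 became 28, 32 and 47 without day 12 non-pregnant replicates 2, 3 and 1, 44 and 55 without day 12 pregnant replicates 3 and 2 and 62 without day 14 pregnant replicate 1. It was 254 without day 14 non-pregnant replicate 2 and 159 without both batch A arrays of that group.

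Cell division genes were lower on day 14 in these ewes, with 33 of 34 members below 0. By their brightest probe sets 0 passed over all genes in limma and 17 adjusted over the list alone, among them the kinase AURKB (-0.66, adjusted p = 0.0639 over all genes) and TPX2 (-0.92). KIF20A, a mitotic kinesin, fell by 0.98 ± 0.16 through its dimmer probe set (adjusted p = 0.0299, past the threshold in 6 of the 12 leave-outs), and its brightest was at -1.25 (adjusted p = 0.0844). The mean was -0.57 ± 0.061, and -0.55 within batch B (camera adjusted p = 1.25e-13, adjusted p = 0.504 with an estimated correlation). Interferon-stimulated genes lay below 0 for 40 of 45 members, 0 over all genes and 6 adjusted over the list alone. Their mean was -0.26 ± 0.037, and -0.21 within batch B (camera adjusted p = 8.42e-06, adjusted p = 0.553 with an estimated correlation). Without day 12 non-pregnant replicate 2, which lay highest of its group, the mean was -0.16 (adjusted p = 0.00319). Fibroblast markers lay below 0 for 12 of 15, with COL1A1 at -0.92 (adjusted p = 0.0914) and MFAP5 at -1.69, 0 over all genes and 4 adjusted over the list alone. Their mean was -0.34 ± 0.122, and -0.25 within batch B (camera adjusted p = 0.00358, adjusted p = 0.634 with an estimated correlation).

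The immediate early and luteolysis response list was higher on day 14 in non-pregnant ewes, with THBS1 past the threshold and 3 of 35 adjusted over the list alone. Its mean was 0.30 ± 0.134, and 0.094 ± 0.154 within batch B (camera adjusted p = 0.00358, adjusted p = 0.726 with an estimated correlation). In the hypoxia response list NDRG1 and SLC2A1 (1.09 ± 0.17, adjusted p = 0.0222, past the threshold in 7 of the leave-outs) rose and VEGFA fell, and 3 were higher and 1 lower adjusted over the list alone. Its mean was 0.30 ± 0.159 and 0.19 ± 0.157 within batch B (camera adjusted p = 0.0145, adjusted p = 0.504 with an estimated correlation). Without day 14 non-pregnant replicate 3 the immediate early mean was -0.035 (adjusted p = 0.525), against 0.57 without replicate 1 or 2 of that group, and without day 14 pregnant replicate 3 the hypoxia list did not pass (adjusted p = 0.0965). Beside all these groups stand the wide spread of the day 14 non-pregnant arrays and their 3′ minus 5′ value of 1.37, against 1.45 on day 12.

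The day 14 comparison and the change in non-pregnant ewes share the 3 day 14 non-pregnant arrays. Of the 94 probe sets, 87 were also called between pregnant and non-pregnant ewes on day 14, each in the opposite direction, where independent lists would share 0.767. Across probe sets, which are not independent replicates, the log2 differences had r = -0.822 and covariance -0.0624. Over 20 simulations of unchanged groups with these shared arrays, r was -0.553 and the covariance -0.0147. The 3 arrays cannot be parted so that each side keeps at least 2, so part of the excess may come from the shared arrays.

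On day 12, the comparison asked whether the gland of a pregnant ewe differs before luteolysis would begin. The smallest p-values belonged to EMG1, a ribosome assembly factor (0.78 ± 0.12), CD164, a sialomucin (-0.62 ± 0.092), and SRSF1, a splicing factor (-0.74 ± 0.11), each with adjusted p = 0.162 (n = 3 per group), so they did not pass. ADH6, an alcohol dehydrogenase, was at 1.13 ± 0.22 (adjusted p = 0.294). Among the reference genes MX1 was at 0.65 ± 0.24 (adjusted p = 0.588), CYP11A1 at 0.16 (adjusted p = 0.769) and ISG15 at -0.20 ± 0.46. In limma 0 probe sets passed, against 1847 at an unadjusted p under 0.05, where chance gives 1201. The count was 5 without day 14 pregnant replicate 1 and 1 without day 14 pregnant replicate 3.

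Oxidative phosphorylation genes, which encode the respiratory chain, were higher as a list in pregnant ewes on day 12. Of 53 members 47 lay above 0, such as NDUFS8 of complex I (0.29 ± 0.11, adjusted p = 0.586) and SDHB of complex II (0.24). In limma 0 passed over all genes and 0 adjusted over the list alone. The mean was 0.14 ± 0.014 and 0.15 within batch B (camera adjusted p = 1.25e-07, adjusted p = 0.917 with an estimated correlation). Fibroblast markers lay below 0 for 11 of 15, such as COL1A1 (-0.51 ± 0.18) and MFAP5 (-0.69), with 0 past the threshold on either count. Their mean was -0.18 ± 0.070, and -0.18 within batch B (camera adjusted p = 0.018, adjusted p = 0.917 with an estimated correlation). Without day 12 pregnant replicate 2 the fibroblast list did not pass (adjusted p = 0.205). Beside both lists, the 3′ minus 5′ difference was 1.57 to 1.60 in the pregnant and 1.42 to 1.47 in the non-pregnant arrays, without overlap. For actin alone the groups overlapped.

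From day 12 to day 14 in pregnant ewes, the comparison asked how the gland that is kept changes over the same days. A2M, a protease inhibitor, was at 1.23 ± 0.23 (adjusted p = 0.84) and AHSG, a plasma protein whose probe set is dim, at -0.66 ± 0.089 (adjusted p = 0.228, n = 3 per group), and neither passed. STAR was at 0.096 and VEGFA at 0.27. In limma 0 probe sets passed, against 1063 at an unadjusted p under 0.05, where chance gives 1201. Interferon-stimulated genes were higher as a list on day 14, with 42 of 45 members above 0, 0 past the threshold over all genes and 7 adjusted over the list alone. Among these were IFIT5 (0.43 ± 0.095, adjusted p = 0.84) and the chemokine CXCL10 (1.03 ± 0.23, adjusted p = 0.84). The mean was 0.36 ± 0.052, 0.27 within batch A and 0.41 within batch B (camera adjusted p = 4.69e-19, adjusted p = 0.354 with an estimated correlation), and the list passed in all 12 leave-outs.

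Oxidative phosphorylation was lower on day 14 in pregnant ewes, with 50 of 53 below 0 and a mean of -0.14 ± 0.011, -0.041 and -0.18 within batches A and B (camera adjusted p = 2.47e-12, adjusted p = 0.499 with an estimated correlation). T and NK cell markers were higher, with CD3G of the T cell receptor complex at 0.74 ± 0.16, 17 of 22 above 0 and 1 past the threshold adjusted over the list alone. Their mean was 0.17 ± 0.046, with 0.11 and 0.19 within the batches (camera adjusted p = 2.39e-05, adjusted p = 0.499 with an estimated correlation). Class II antigen presentation, which shows peptides to helper T cells, had a mean of 0.29 ± 0.096, 0.38 and 0.25 within the batches (camera adjusted p = 0.000388, adjusted p = 0.601 with an estimated correlation). Macrophage markers, with CYBB at 0.75, had a mean of 0.17 ± 0.044, 0.25 and 0.13 within the batches (camera adjusted p = 0.00705, adjusted p = 0.863 with an estimated correlation). Cell division genes had a mean of -0.18 ± 0.023, with 0.24 within batch A, from 1 array per group, and -0.39 within batch B, from 2 per group (camera adjusted p = 0.000823, adjusted p = 0.863 with an estimated correlation).

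No member of the oxidative phosphorylation, class II, macrophage or cell division list passed over all genes or adjusted over the list alone in pregnant ewes. Without day 12 pregnant replicate 3 the class II and macrophage lists did not pass (means 0.18 and 0.032, adjusted p = 0.14 and 0.765). Without day 14 pregnant replicate 2 neither they (means 0.17 and 0.056, adjusted p = 0.0837 and 0.391) nor cell division (-0.082, adjusted p = 0.35) did, and the T and NK cell mean was 0.10. Cell division did not pass without day 12 pregnant replicate 1 (-0.11, adjusted p = 0.14), and its mean was -0.33 and -0.35 without day 12 and day 14 pregnant replicate 3. The macrophage mean was 0.27 without day 12 pregnant replicate 2. The 3′ minus 5′ difference was 1.58 on day 12 and 1.52 on day 14 in these ewes. This comparison shares the day 12 pregnant arrays with the day 12 comparison, with r = -0.531 across probe sets against -0.48 in simulated unchanged groups and covariance -0.0149 against -0.0111. It shares the day 14 pregnant arrays with the day 14 comparison, with r = 0.23 against 0.481 and covariance 0.00992 against 0.0111.

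The interaction term asked which genes differ in their response to pregnancy between the days. It was negative, with the difference between pregnant and non-pregnant ewes lower on day 14 than on day 12, for CRYAB (-1.96 ± 0.22, adjusted p = 0.013), F2RL2 (-2.16 ± 0.26, adjusted p = 0.0132), F2RL1 (-2.57 ± 0.37, adjusted p = 0.0394) and CDH1, the epithelial cadherin (-1.74 ± 0.27, adjusted p = 0.0481). Outside the day 14 non-pregnant group the levels of F2RL1 and CDH1 were at most 3.82 and 4.07 as group means, among the dimmest, so the sizes of these terms are uncertain. It was positive for the growth factor TGFB2 (1.65, adjusted p = 0.0456). Interferon-stimulated genes had a positive term as a list, with a mean of 0.62 ± 0.068, 17 of 45 past the threshold adjusted over the list alone and 0 over all genes. Among the 17 were IFIT5 (0.82, adjusted p = 0.0917) and PARP9 (1.01, adjusted p = 0.109). That list passed in all 12 leave-outs (camera adjusted p = 1.99e-16, adjusted p = 0.495 with an estimated correlation). VEGFA (1.79 ± 0.35, adjusted p = 0.132) and STAR (0.74, adjusted p = 0.272) did not pass.

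In limma 21 probe sets passed the interaction term, 6 positive and 15 negative, of which 12 named a gene, with 2262 at an unadjusted p under 0.05. Without a batch term or with batch as a random block 24 were positive and 26 negative, and at an unadjusted p with a 1.5-fold change 467 were positive and 441 negative. Within batch B the term was -1.68 for CRYAB, -2.13 for F2RL2, -2.46 for F2RL1, -1.58 for CDH1 and 1.53 for TGFB2. CRYAB passed in 9 of the 12 leave-outs, and not without day 12 non-pregnant replicate 3, day 12 pregnant replicate 2 or day 14 pregnant replicate 3 (adjusted p = 0.056, 0.0901 and 0.0787). F2RL2, F2RL1, CDH1 and TGFB2 passed in 7, 4, 4 and 3, with the highest adjusted p of 0.112, 0.155, 0.196 and 0.193. The count of 21 became 3 and 1 without day 12 pregnant replicates 1 and 2, and 8, 6 and 1 without day 12 non-pregnant replicates 1, 2 and 3. It was 10, 6 and 2 without day 14 pregnant replicates 1, 2 and 3, and 56 and 76 without day 14 non-pregnant replicates 1 and 2.

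Averaged over both days, the pregnancy effect asked which differences the larger groups of 6 ewes show. Such an average can come from 1 day alone, and of the lists named here only oxidative phosphorylation passed on day 12. The interferon-stimulated mean was -0.081 on day 12 and 0.54 on day 14. The interferon-stimulated list had a mean of 0.23 (4 of 45 higher over all genes and 18 adjusted over the list alone, camera adjusted p = 6.33e-07, adjusted p = 0.649 with an estimated correlation). Progesterone synthesis and cholesterol supply had a mean of 0.12 (2 higher over all genes, 5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.242 with an estimated correlation). Class I antigen presentation had a mean of 0.16 (1 higher over all genes and 9 adjusted over the list alone, camera adjusted p = 0.00366, adjusted p = 0.665 with an estimated correlation). Oxidative phosphorylation (mean 0.087, camera adjusted p = 0.000593) and cell division (0.17, adjusted p = 0.00551) were higher, with adjusted p = 0.688 and 0.739 with an estimated correlation. Hypoxia response (-0.17, adjusted p = 0.00785), matrix remodelling (-0.14, adjusted p = 0.00785) and the immediate early list (-0.16, adjusted p = 0.0125) were lower, with adjusted p = 0.242, 0.649 and 0.739 with an estimated correlation.

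In limma 208 probe sets passed for the averaged effect, 48 higher and 160 lower in pregnant ewes, and 145 of them named 133 genes. Without day 14 non-pregnant replicate 3 the immediate early mean was 0.10 (adjusted p = 0.96) and the matrix list did not pass (0.0577), nor did that list without day 12 pregnant replicate 3 (0.055). Without day 14 pregnant replicate 3 the cell division, hypoxia and immediate early lists did not pass (0.141, 0.0629 and 0.0673), and the means of cell division and oxidative phosphorylation were 0.084 and 0.058. The immediate early mean was -0.23 and -0.35 without day 14 non-pregnant replicates 1 and 2 and -0.10 without day 12 pregnant replicate 3, where the matrix mean was -0.090. The count of 208 became 112, 92 and 18 without day 12 pregnant replicates 1, 2 and 3 and 64, 92 and 82 without day 12 non-pregnant replicates 1, 2 and 3. It was 50 and 76 without day 14 pregnant replicates 2 and 3, 348 without day 14 non-pregnant replicate 2, and 55 without both batch A arrays of that group.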

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

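The tests of array batch along the first principal component, of a loss of luteal cells and of a fall in non-pregnant ewes alone were chosen only after the result was seen. So were the reading of RNA integrity as a covariate or over the days in pregnant ewes, and the errors over arrays. The genes and lists listed next drew attention because the pregnancy effect differed between day 12 and day 14 by the interaction term.

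There were 21 probe sets with such a difference. In log2 units it was negative for CRYAB (-1.96), F2RL2 (-2.16), the insulin receptor INSR through a dim probe set (-1.95, with -0.095 for its brightest), the sterol transporter ABCG8 (-0.98), F2RL1 (-2.57), ABCC3 (-2.19), EMG1 (-1.17), the smooth muscle protein CNN1 (-1.43), the proton pump subunit ATP6V1E1 (-0.93) and CDH1 (-1.74). It was positive for PPM1K, a mitochondrial phosphatase, through a dim probe set (1.70, with 0.80 for its brightest), and for TGFB2 (1.65). Over the 12 leave-outs of 1 array the term passed in 5 for ABCC3, ABCG8 and the dim INSR probe set. It passed in 4 for EMG1 and the dim PPM1K probe set, in 3 for ATP6V1E1 and in 2 for CNN1. As lists, interferon-stimulated genes (0.62), cell division (0.39), fibroblasts (0.35) and T and NK cells (0.19) had positive means, and the immediate early and luteolysis response (-0.44) and oxidative phosphorylation (-0.10) had negative ones. None of these lists passed with an estimated correlation (adjusted p = 0.495, 0.662, 0.662, 0.662, 0.816 and 0.816).

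Over the 12 leave-outs of 1 array the interferon-stimulated list passed in 12. Cell division passed in 11, with a mean of 0.12 without day 14 pregnant replicate 3 (adjusted p = 0.158) and 0.25 without day 12 non-pregnant replicate 2, where it passed. The immediate early list passed in 9, and not without day 14 pregnant replicate 3 (-0.36, adjusted p = 0.221), day 14 non-pregnant replicate 3 (-0.10, adjusted p = 0.152) or day 12 pregnant replicate 1 (-0.31, adjusted p = 0.0595). Its mean was -0.705 and -0.70 without day 14 non-pregnant replicates 1 and 2. Oxidative phosphorylation passed in 9, and not without day 14 non-pregnant replicate 1 (-0.022, adjusted p = 0.517), day 12 pregnant replicate 2 (adjusted p = 0.0883) or day 14 pregnant replicate 2 (adjusted p = 0.0629), and its mean was -0.20 without day 14 pregnant replicate 3. Fibroblasts passed in 9, and not without day 14 pregnant replicate 3 or 1 or day 12 pregnant replicate 2 (adjusted p = 0.11, 0.0537 and 0.0883). T and NK cells passed in 7. They did not pass without day 12 pregnant replicate 2, day 14 non-pregnant replicate 1 or 2, day 12 non-pregnant replicate 2 or day 14 pregnant replicate 2 (adjusted p = 0.0883, 0.0797, 0.0684, 0.0782 and 0.0721).

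Of 100 splits of the arrays drawn for the interaction, 9 gave at least the 21 probe sets of the real one, with 90 as the highest of the others, so chance cannot be excluded. The 8 other splits with as many all kept the real day 14 groups together, and splits that mixed those groups gave at most 2, which points to a structure of the samples on day 14. For the averaged effect 1 of 100 splits, the real one with 208, gave as many, with 90 as the highest of the others. This argues against chance only for the labels of both days shuffled at once. The splits drawn did not include a swap of the labels of a single day, which turns each of these terms into the other. The 10 other splits that kept the real day 14 groups gave 9 to 90, and those that mixed these groups at most 1. The counts thus follow the day 14 groups, but the splits of either day alone are too few for a share under 0.05. Chance is therefore not excluded for the groups of day 14 or of day 12 alone. Each comparison of 3 ewes with 3 has only 10 splits, too few for a share under 0.05. The real value was 348 on day 14 (1 split with as many, highest other 0), 94 in non-pregnant ewes (1, highest other 0), 0 on day 12 (10, highest other 0) and 0 in pregnant ewes (10, highest other 0).

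The day 14 non-pregnant arrays stood apart from the other 9 and among themselves. Array batch as the whole cause is argued against, since batch A and B arrays of the pregnant groups lay apart on the first component by only 5.88% of the distance in the day 14 non-pregnant group. RNA degradation was to give these arrays the highest 3′ minus 5′ differences, by the bound set beforehand. Their mean of 1.37 was instead lower than in all other arrays (1.42 or more), which met neither bound. If a higher value does mean more degradation, the lower value argues against more of it in these arrays. A difference in RNA integrity stays open. With the 3′ minus 5′ difference as a covariate the day 14 groups lay apart by -44.8 (SE 6.12) on the first component, against -38.5 (SE 4.24) without it. What it would give on day 12 missed the value found there by -23.3 (SE 17.4), under 2 standard errors. A loss of luteal cells that leaves all other cell types in a higher share would raise their lists alike in non-pregnant ewes. From day 12 to 14 the fibroblast list instead fell there (-0.34), with the macrophage list at 0.029. Such a loss still stays open, because fibroblast markers lay below macrophage markers (-0.37) by more than 2 standard errors over members (0.168) but not over arrays (0.303). Ewes reaching luteolysis at different hours by day 14 may be another reason, which the design names only as day and status and which was not tested.

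Interferon-stimulated genes were higher in pregnant ewes on day 14. Array batch as the whole cause is argued against, since the list's mean was 0.54 with batch in the model (SE 0.105 over arrays), with 0.50 as the smaller mean within a batch (SE 0.0753 over members), although each batch had a group of 1 array. RNA integrity stays open as a part of it. Although the values of actin and of GAPDH taken singly overlapped, the mean 3′ minus 5′ differences of the day 14 groups did not, coming as close as 1.439 and 1.433. With that difference as a covariate the list was at 0.44 (SE 0.165 over arrays). On day 12 the list lay below the size it would give by 0.50 (SE 0.269), under 2 standard errors. RNA integrity as the whole cause, as far as the 3′ minus 5′ difference shows it, is argued against by pregnant ewes. In them the list rose by 0.36 from day 12 to 14 (SE 0.101 over arrays). Their 3′ minus 5′ difference did not rise with it (1.58 ± 0.016 and 1.52 ± 0.0823, SD). T cell and macrophage markers together shifted by less than the list (-0.44, SE 0.0789 over members and 0.096 over arrays). This argues against more of these cells only if the list moves as their markers do, so they stay open as a part. From day 12 to 14 in pregnant ewes T and NK cell markers rose by 0.11 and 0.19 within batches A and B. Macrophage markers rose by 0.25 and 0.13. A fall in non-pregnant ewes alone is argued against by the change of 0.36 in pregnant ewes (SE 0.101 over arrays). That change shares the day 14 pregnant arrays with the pattern and had adjusted p = 0.354 at an estimated correlation. A response to the conceptus may be a reason too, as a hypothesis from the same arrays with adjusted p = 0.191 at an estimated correlation. Its share and that of RNA integrity cannot be told apart here.

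Oxidative phosphorylation genes were higher in pregnant ewes on day 12. A shift of all bright probe sets is argued against by the list's place at percentile 100 of 10000 random lists of like level (mean 0.14, against an upper bound of 0.055 for theirs), and 1 day 12 array alone by a highest adjusted p of 8.49e-05 over the 6 leave-outs of those arrays. RNA integrity stays open, since the mean 3′ minus 5′ difference of the groups (0.129, higher in pregnant ewes) came without overlap, although the values of actin alone overlapped. With the 3′ minus 5′ difference as a covariate the list was at 0.19 (SE 0.0549 over arrays), no smaller than the 0.14 without it. What it would give on day 14 missed the value found there by 0.14 (SE 0.124), under 2 standard errors. The difference met the bound set beforehand against degradation, which counted only a lower value in pregnant ewes as a cause. The other direction, in which degradation would favour short transcripts, was considered only after the value was seen and was not tested directly. The ribosomal protein list, of mostly short transcripts too, moved by only 0.031 ± 0.0094. With an estimated correlation the list did not pass (adjusted p = 0.917). The groups differ in pregnancy and, without overlap, in the 3′ minus 5′ difference, so pregnancy and RNA integrity cannot be told apart here.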

How the results depend on the processing

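The fit without both batch A arrays of the day 14 non-pregnant group and the comparison of results with shared arrays were the tests chosen only after the result was seen. No paired analysis was possible because replicate numbers were given in accession order and pair no ewes. Within batch A no value could be had for comparisons with day 12 non-pregnant ewes, and a fit of only the groups compared has no counterpart for the interaction or the average. Of the log2 differences of named genes, 4423 kept direction and side of the threshold across alternatives, 554 lost and 102 gained the threshold and 54 reversed; of list shifts 503 kept both, 141 lost the threshold and 4 reversed, all of the immediate early list. No detection calls were used, so how far signal stood above background is unknown. The cause was not tested.

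On day 14 the count of 348 became 531 without a batch term (325 of them shared), 24 with only the groups compared, 141 with array weights (33 higher), 163 within batch B (85 shared, 27 higher), 0 within batch A in limma (1498 at an unadjusted p under 0.05), 174 without both batch A arrays (94 shared) and 845 at an unadjusted p with 1.5-fold, with 88 to 510 over the leave-outs. In non-pregnant ewes 94 became 415 without a batch term, 462 with a random block, 1 with only the groups compared, 142 within batch B, 159 without both batch A arrays (60 shared) and 745 at an unadjusted p, with 28 to 254 over the leave-outs. For the interaction 21 became 50 without a batch term, 50 with a random block, 13 without the dimmest probe sets, 59 within batch B, 59 without both batch A arrays and 908 at an unadjusted p, with 1 to 76 over the leave-outs. For the average 208 became 57 within batch B, 55 without both batch A arrays and 91 with 1.5-fold, with 18 to 348 over the leave-outs. On day 12 limma's 0 became 1 with only the groups compared and 202 at an unadjusted p with 1.5-fold, with 0 to 5 over the leave-outs. In pregnant ewes 0 became 92 at an unadjusted p with 1.5-fold and stayed 0 over the leave-outs.

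Of the lists, 0 passed with an estimated correlation in any comparison. On day 12, 2 lists became 0 with fry and 1 without a batch term (2 to 6 over the leave-outs). On day 14, 9 became 3 with fry and 4 without both batch A arrays (2 to 12). In non-pregnant ewes 5 became 0 with fry, 8 with the mean over probe sets, 8 without a batch term and 3 without both batch A arrays (5 to 14). In pregnant ewes 6 became 0 with fry (3 to 8), and for the interaction 6 became 0 with fry (3 to 9). For the average 8 became 1 with fry and 5 without both batch A arrays (5 to 12). The excess of the immediate early list over other genes was -0.70 to 0.037 over the leave-outs on day 14, -0.030 to 0.59 in non-pregnant ewes and -0.36 to 0.086 for the average, with each change of sign without day 14 non-pregnant replicate 3. For the average it was 0.0015 without both batch A arrays of that group.

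No gene that passed reversed. On day 12 STAR (0.0012) was -0.024 without a batch term, -0.026 with a random block, -0.10 with only the groups compared, -0.022 with array weights, -0.10 within batch B, -0.067 without both batch A arrays and -0.10 to 0.092 over the leave-outs. VEGFA (-0.0068) was 0.029, 0.032 with a random block, 0.013 after quantile normalization and -0.21 to 0.20. HSD3B1 (0.12) was -0.0043 and -0.014 with a random block, and ISG15 (-0.20) was -0.64 to 0.37. On day 14 LHCGR (0.37) was -0.053 within batch B and -0.025 without both batch A arrays. In non-pregnant ewes MX1 (0.046) was -0.13 without a batch term, -0.14 with a random block, -0.071 with only the groups compared, within batch B and without both batch A arrays, and -0.18 to 0.21. There ISG15 (-0.46) was -0.89 to 0.11, and OXT (-0.050) was 0.0055 after quantile normalization and -0.095 to 0.035. In pregnant ewes the values within batch A were 0.062 for BIRC5 (-0.41), -0.069 for CYBB (0.75), -0.35 for MX1 (0.43), -0.40 for PTGFR (0.053), -0.053 for STAR (0.096) and 0.34 for TK1 (-0.27). Within batch B they were 0.025 for CYP11A1 (-0.070) and 0.022 for HSD3B1 (-0.024). Over the leave-outs CYP11A1 was -0.14 to 0.054, HSD3B1 -0.096 to 0.12 and PTGFR -0.080 to 0.36. The interaction of OXT (-0.049) was 0.030 without a batch term, 0.035 with a random block, 0.013 within batch B and -0.13 to 0.024.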

Other observations

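The array batch, luteal cell, non-pregnant fall and RNA integrity tests given earlier were the ones chosen only after the result was seen, and the genes named in this part, apart from BMPR1B, were also chosen after their values were seen. Some further genes passed in limma on day 14. IGFBP3, which binds insulin-like growth factors, was lower in pregnant ewes (-1.50 ± 0.22, adjusted p = 0.00724) and rose in non-pregnant ewes from day 12 to day 14 (1.31 ± 0.24, adjusted p = 0.0462, past the threshold in 1 of the 12 leave-outs). CNN1, a calponin of smooth muscle, was lower in pregnant ewes (-1.54 ± 0.15, adjusted p = 0.000974) and rose over the days in non-pregnant ewes (1.38 ± 0.16, adjusted p = 0.00525), while the smooth muscle and pericyte list did not shift past the threshold (adjusted p = 0.841). BMPR1B, a receptor for bone morphogenetic proteins, was lower in pregnant ewes (-1.10 ± 0.16, adjusted p = 0.00724) and rose in non-pregnant ewes (0.97 ± 0.17, adjusted p = 0.0419, past the threshold in 3 of the 12 leave-outs). IFI30, a lysosomal thiol reductase, was lower in pregnant ewes (-1.51 ± 0.26, adjusted p = 0.0193), and BCL2A1, which restrains apoptosis, was higher (0.80 ± 0.17, adjusted p = 0.0446). INHBA, a subunit of activin, was at -2.88 ± 0.63 and missed the threshold (adjusted p = 0.05001). On day 14 BMPR1B, IGFBP3 and IFI30 did not pass without day 14 pregnant replicate 3 (adjusted p = 0.0788, 0.0726 and 0.115), nor IFI30 without replicate 1 of that group (0.0597). BCL2A1 passed in 3 of the 12 leave-outs, with 0.41 without day 14 pregnant replicate 3 (adjusted p = 0.172), and CNN1 passed in each of them in both comparisons.

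Prostaglandin and receptor genes moved in both directions on day 14. Adjusted over the list alone, 3 prostaglandin genes were higher and 2 lower in pregnant ewes, although none passed over all genes. The importer SLCO2A1 (0.73 ± 0.19, list adjusted p = 0.0215) and the degrading enzyme HPGD (0.89 ± 0.31, 0.0484) were higher, and the prostacyclin synthase PTGIS (-0.87 ± 0.21, 0.0215) and the reductase AKR1B1 (-0.53 ± 0.17, 0.0336) were lower. Among receptors 4 were higher and 3 lower adjusted over the list alone, with PRLR for prolactin (0.52 ± 0.14, list adjusted p = 0.0319) and the dim ESR1 for oestrogen (0.43 ± 0.13, 0.0319) higher and PTGER4 for prostaglandin E2 lower (-0.83 ± 0.28, 0.0447). Of the 23 receptor genes 4 are also in another list.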
